A study of Mus musculus with 7 samples.

How the data were processed

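RNA of dendritic cells from cultures of sorted common myeloid progenitors was measured on 7 one-colour Agilent arrays. It was amplified and labelled with Cy3, per the labels' protocols. The labels assign 3 arrays to the knockout group and 4 to the control group, and the source names of the knockout arrays carry an abbreviation whose meaning is not given in the sources used here. The series title speaks of dendritic cell progenitors while the labels of each array speak of dendritic cells. The tamoxifen schedule ran from day 1 to day 10, per the labels' protocols.

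The scanner files hold spot intensity as deposited by the authors, extracted with Agilent Feature Extraction 10.7.3.1 per the file headers, including a background-corrected processed signal, the median signal and the local background median. Each array has 62976 spots, of which 3671 are control spots, and the 75th percentile of the processed signal lay between 2671 and 3825 intensity units. The deposited series table holds log2 values, each probe centred on its median over the 7 arrays. This was found by comparison, since scale, centring and direction are not stated by the submitters: differences between arrays had a correlation of at least 0.99996 and a slope between 0.99999 and 1.00011 with those of the scanner values, in the same direction. Column medians of that table were 0 for each array except replicate 3 of the arrays labelled knockout, at -0.02. It was used as an alternative.

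For the main values, log2 of the processed signal had each array's 75th percentile over non-control spots subtracted, outlier spots were left out, and spots of one probe were averaged. A probe was tested if well above background on at least 3 of 7 arrays, which kept 34133 of 55681 probes. Probes were named by matching their RefSeq accession, without versions, to a table of assembly GRCm38.p6, and 26413 probes (47.4%) matched, which is 79.9% of the 33064 probes with such an accession. The arrays were annotated on an older build, so no coordinates are given. Each gene was represented by its tested probe with the highest mean signal. Of 104 named genes, 23 had several tested probes, and for 3 of them (Siglech, Tcf4 and Esr1) another probe had the opposite sign.

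Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Residual degrees of freedom were 5 and prior degrees of freedom 3.09. Gene lists were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, whose directional test asks whether genes of a list move on balance one way and whose mixed test asks whether they change in either direction. The adjusted p of lists covers the 27 lists. The lists, the named gene rule, the tests and most alternatives were fixed before the data were examined. The rule names Gata2, the 10 genes with the largest change each way among those past the threshold with separated groups, the genes the study names, and up to 4 members per direction of each list past the threshold, or up to 2 where none passes, as values only. A further 21 genes were chosen after their values were seen, some of them the largest changes among genes measured in both groups. Lower bounds compare the brighter group's mean with, per array, the higher of the dimmest signal well above background and the probe's own value.

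The fit was tested on simulated data for this comparison with the means and spreads of its 14547 genes, in which 200 genes were changed. Over 5 runs, 61.8% of the 100 genes changed by 1 on the log2 scale were called, 95.8% of the 100 changed by 2, and 4.72% of calls were unchanged genes. In 20 simulated runs a list shifted by 0.5 was called 20 times, and 1 other list was called over all runs. These simulated genes were independent, which real list members are not. The number of arrays limits the precision.

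All arrays lay on 1 slide and came from 1 scan, so no slide or scan block was possible. Arrays correlated between 0.9856 and 0.9919 within groups and between 0.9791 and 0.9848 between groups across genes, and none were identical. The design named the mean signal for normexp, but the median signal was used because the scanner files as used here held no mean signal column. Alternatives covered background correction, normalization, the series table, the filter, outlier spots, the variance model, array weights, the probe rule, thresholds, a replicate block and each array left out. Added after seeing the data were a signal floor common to all arrays, a floor at each array's own dimmest signal well above background, a filter on genes measured in both groups, and lists without the genes the study names and without Rag1. One gene that the rule takes is not reported here.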

Results

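Gene expression was measured on 7 one-colour microarrays of dendritic cells grown from mouse common myeloid progenitors, the bone marrow cells from which granulocytes, monocytes, red cells and platelets descend. The donors were C57BL/6 mice with a floxed Gata2 gene, which encodes a zinc finger transcription factor of blood progenitors. Mice of one group also carried a tamoxifen-inducible Cre recombinase, and 3 arrays were labelled knockout. The 4 control arrays came from floxed mice without the Cre, which were also treated with tamoxifen. Progenitors were sorted on days 20 to 22 of the tamoxifen schedule and cultured on bone marrow feeder cells of another strain with FLT3 ligand at 200 ng/ml. The labels do not say how the dendritic cells were separated from the feeder cells, nor that replicates came from separate animals, so p-values measure only the spread between these arrays. Between 61.5% and 67.4% of spots were well above background on the arrays labelled knockout, and between 54.1% and 56.9% on the control arrays.

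Gata2 itself was brighter in the arrays labelled knockout, against what the label would give for a probe in the deleted part of the gene. Its single probe read 2.99 ± 0.06 (SD, n = 3) on the log2 scale relative to the array's 75th percentile, against 0.17 ± 0.29 (SD, n = 4) in the controls. The difference was 7.08-fold (log2 fold change 2.82, SE 0.17, limma adjusted p = 0.000153), and all 3 arrays labelled knockout lay above all 4 controls. Whether this probe lies inside the deleted part is not given in the sources used here, so it cannot settle the labels. Every direction given here is therefore that of the arrays as labelled.

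**Figure D1:**
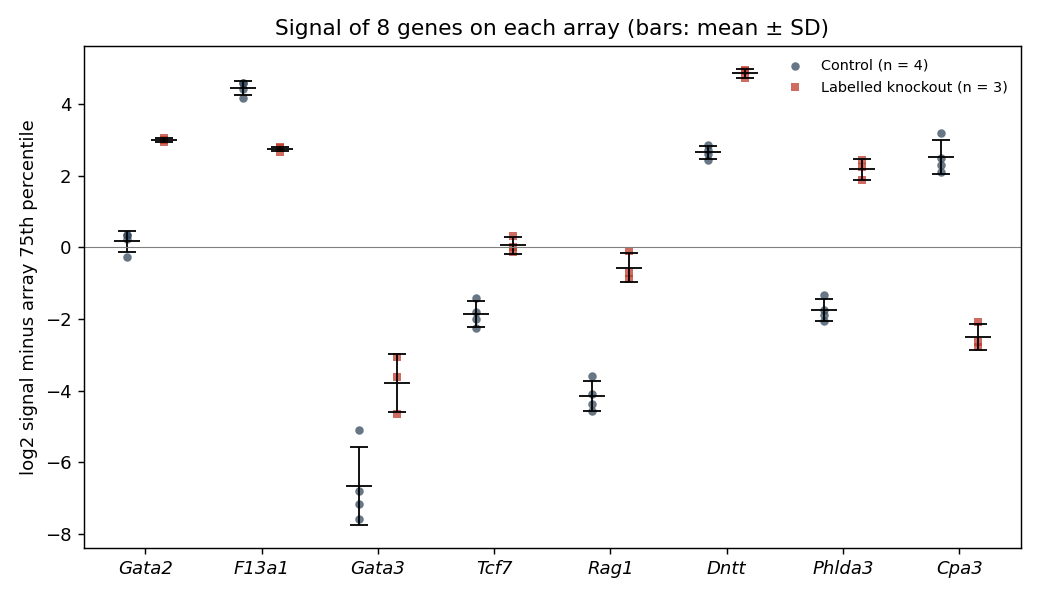
Signal of 8 genes on each array, as log2 intensity minus the array's 75th percentile (vertical axis), for the 4 control arrays (circles) and the 3 arrays labelled knockout (squares), with bars for the mean and SD. Gata2 stands at 2.99 in the arrays labelled knockout and 0.17 in the controls, Cpa3 shows the opposite order, and Gata3 was not well above background on any control array.

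The comparison of the 2 groups asks which genes of the cultured cells differ when Gata2 is targeted in the donor. It cannot tell a change within dendritic cells from a change in which cells were present. In the arrays labelled knockout, the gene lists of mast cells and basophils and of monocytes and macrophages were shifted down. That of T cell receptor complex and signalling genes was shifted up. These 3 lists were called also with an estimated correlation (camera adjusted p = 0.0302, 0.0344 and 0.0344). Among 14547 genes, 217 were higher and 201 lower. Of these, 176 of the higher and 145 of the lower genes differed at least 2-fold. Of the higher genes, 54 were read from a probe not well above background on any control array, and 11 of the lower genes from a probe not well above background on any array labelled knockout. Each group occupied a slide row of its own, and by the labels only the knockout group carried the Cre. Neither row nor Cre can therefore be told apart from group, for any gene or list.

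**Figure D2:**
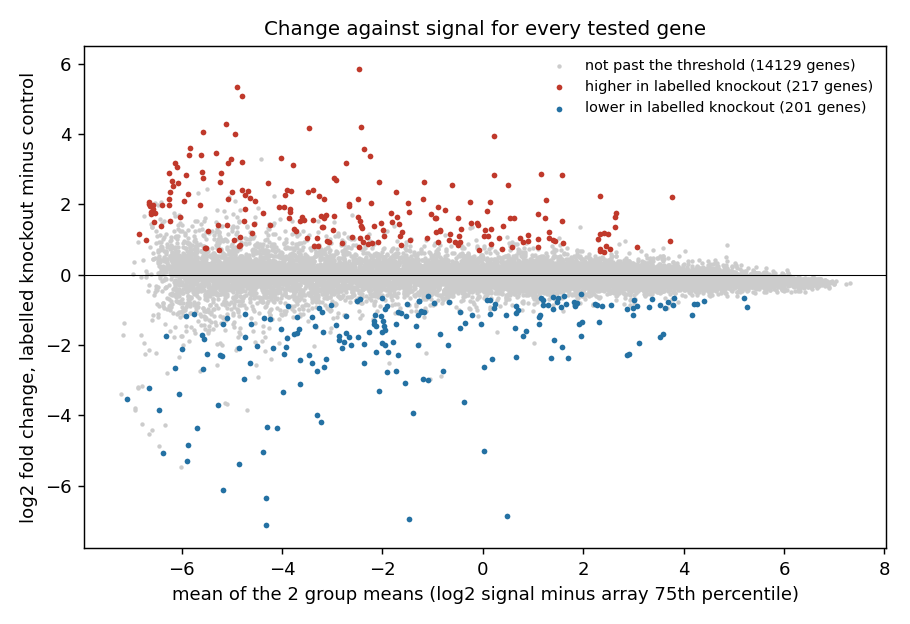
Log2 fold change (arrays labelled knockout minus controls, vertical axis) against the mean of the 2 group means (log2 intensity minus the array's 75th percentile, horizontal axis), with 1 point per tested gene. The 217 higher genes are red, the 201 lower genes blue and the others grey.

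Negative control spots were 1.19 log2 units dimmer in the arrays labelled knockout after scaling (-8.78 ± 0.41, SD, n = 3, against -7.59 ± 0.14, SD, n = 4; two-sided exact permutation p = 0.02857, the smallest that 35 splits can give). Spike-in spots had a median of 1.48 ± 1.48 (SD, n = 3) in the arrays labelled knockout and 1.08 ± 0.29 (SD, n = 4) in the controls (two-sided exact permutation p = 0.6286). Replicate 2 labelled knockout stood at -0.20, against 2.61 and 2.01 on replicates 1 and 3. Without a filter on background 365 genes were higher and 2483 lower, with normexp background correction and the same scaling 195 and 283, with array weights 699 and 822, and with values under each array's own dimmest signal well above background raised to it, chosen after seeing the data, 224 and 311. Arrays were left out 1 at a time. The higher count fell by over 1.5 times without replicate 1, 2 or 3 of the arrays labelled knockout, where 98, 123 and 85 of the 217 genes kept their call and 164 were still tested. The lower count fell likewise without replicate 3 of that group or control replicate 3, where 103 and 125 of the 201 genes kept theirs. Where a gene was not well above background on any array of a group, the fold is given as "at least", against each array's own dimmest signal counted as well above background. The adjusted p printed beside such a fold is that of the main fit without a floor, and does not test the bound. That signal lay at -6.65 ± 0.38 (SD, n = 3) in the arrays labelled knockout and -5.51 ± 0.13 (SD, n = 4) in the controls. These folds are bounds against that floor alone, and are smaller with a floor common to all arrays, chosen after seeing the data and set at the highest of these signals.

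Matn1, which encodes the cartilage matrix protein matrilin-1, rose 58.0-fold (log2 fold change 5.86, SE 0.40, adjusted p = 0.000187). Its probe was well above background on 1 of 4 controls, and the rise was 50.1-fold with each array's own floor. Tnfsf4, the ligand of the costimulatory receptor OX40, was at least 9.68-fold higher (adjusted p = 2.6e-06), and Ddit4l at least 9.59-fold higher (adjusted p = 0.000235). With the common floor their log2 fold changes were 3.09 and 3.07. Zfp365 rose 18.3-fold (adjusted p = 0.00201), Phlda3 15.3-fold (adjusted p = 0.000117) and Inka2 18.1-fold (adjusted p = 0.0165). Inka2 was well above background on 2 of 4 controls, and rose 12.2-fold with each array's own floor and 11.7-fold with the common floor, less than Phlda3. Its call was lost without replicate 1, 2 or 3 of the arrays labelled knockout (adjusted p from 0.057 to 0.0722). Fat1, Mmp2, Cacng2 and Foxl1 were at least 5.83-fold, 5.99-fold, 3.92-fold and 2.81-fold higher, or 5.12-fold, 5.26-fold, 3.44-fold and 2.47-fold with the common floor. The calls of Cacng2 and Foxl1 were lost with the common floor (adjusted p = 0.0713 and 0.265), and that of Foxl1 also with each array's own floor (adjusted p = 0.0991).

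Prss34, a basophil protease, fell 123-fold (adjusted p = 0.00018) and Thbs1, which encodes thrombospondin-1 of platelet granules, 115-fold (adjusted p = 3.11e-05). Klk1b11, a kallikrein whose family members share much of their sequence, and Tspan12 were each well above background on 1 of 3 arrays labelled knockout. With each array's own floor, they fell 52.7-fold and 40.6-fold (adjusted p = 9.68e-06 for both), and with the common floor 23.6-fold and 18.2-fold. Cyp11a1, the enzyme of the first step of steroid hormone synthesis, was at least 23.2-fold lower (adjusted p = 5.42e-06). Pgr, the progesterone receptor, was at least 22.4-fold lower (adjusted p = 0.000234) and Samd5 at least 7.05-fold lower (adjusted p = 0.000153). With the common floor Cyp11a1 was 9.24-fold, Pgr 9.00-fold and Samd5 2.81-fold lower, and the call of Samd5 was lost (adjusted p = 0.0558).

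Gata3 and Tcf7 were named by the study on these arrays, so their direction is not independent evidence. Gata3, which encodes a transcription factor of T cell development, was at least 3.21-fold higher (adjusted p = 0.0472). Tcf7, another such factor, rose 3.79-fold (log2 fold change 1.92, SE 0.22, adjusted p = 0.00242). With the common floor, the log2 fold change of Gata3 was 1.49 (adjusted p = 0.114) and did not pass. The Gata3 call was also lost with quantile normalization (adjusted p = 0.054), with normexp and percentile scaling (log2 fold change 1.10, adjusted p = 0.0761), with the probe of largest interquartile range (adjusted p = 0.0544) and without control replicate 1 (adjusted p = 0.0964), 2 (adjusted p = 0.103) or 3 (adjusted p = 0.122). Adjusted p ranged from 0.00662 to 0.122 over the alternatives for Gata3, which was not tested without an array labelled knockout.

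Mast cell and basophil genes had the lowest median of the 27 lists. Of 14 measured members, 8 fell, and the median log2 fold change was -1.94 (camera adjusted p = 3.68e-10; adjusted p = 0.0302 with an estimated correlation). Cpa3, the mast cell carboxypeptidase, fell 32.5-fold (adjusted p = 0.000117), and Ms4a2, the beta chain of the IgE receptor, was at least 4.38-fold lower (adjusted p = 0.00018), or 1.75-fold lower with the common floor, where its call was lost (adjusted p = 0.0992). Fcer1a, the alpha chain, was well above background on 2 of 3 arrays labelled knockout and fell 20.1-fold with each array's own floor (adjusted p = 0.000258) and 11.2-fold with the common floor. Its call was lost with the replicate block (adjusted p = 0.068). Adjusted over the list alone, 8 members fell. The list's median was between -1.26 and -0.90 with normexp correction, without a filter, over genes above background in both groups or on all arrays, and with the common floor.

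Of 21 monocyte and macrophage genes, 11 fell and none rose, with a median of -0.88 (camera adjusted p = 8.53e-18; adjusted p = 0.0344 with an estimated correlation), and 17 fell adjusted over the list alone. Maf fell 3.44-fold (adjusted p = 0.00765) and F13a1, a coagulation factor chain, 3.23-fold (adjusted p = 0.000489). With the replicate block the call of Maf was lost (adjusted p = 0.0678). C1qc, a chain of complement C1q, was well above background on 1 of 3 arrays labelled knockout and fell 7.34-fold with each array's own floor (adjusted p = 0.00931). Its call was lost with the common floor (log2 fold change -1.91, adjusted p = 0.113) and without replicate 1 or 3 labelled knockout (adjusted p = 0.0708 and 0.0779). Phagocytic and pattern recognition receptors had a median of -0.70, with 4 of 19 lower and 14 adjusted over the list alone (camera adjusted p = 1.04e-10; adjusted p = 0.0659 with an estimated correlation). The scavenger receptors Cd36 and Stab1 fell 5.64-fold and 4.21-fold. The call of Cd36 was lost with the common floor (adjusted p = 0.119) and without control replicate 4 or replicate 1, 2 or 3 labelled knockout (adjusted p from 0.0579 to 0.0993). Of 15 megakaryocyte and platelet genes, 6 fell, 8 adjusted over the list alone, with a median of -0.75 (camera adjusted p = 1.88e-09; adjusted p = 0.0742 with an estimated correlation). Ppbp, a platelet chemokine, fell 5.10-fold and Gp1ba, a receptor for von Willebrand factor, 2.75-fold. Both calls were lost with the common floor (adjusted p = 0.0735 and 0.0875), without control replicate 1 and without replicate 1, 2 or 3 labelled knockout. That of Ppbp was also lost without control replicate 2 and that of Gp1ba without control replicate 3. Adjusted p without these arrays was from 0.0514 to 0.0775 for Ppbp and from 0.0886 to 0.156 for Gp1ba. The Gp1ba call was also lost with quantile normalization (adjusted p = 0.0567) and the probe of largest interquartile range (adjusted p = 0.0502).

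Of 19 neutrophil and granule genes, 5 fell, 13 adjusted over the list alone, with a median of -1.01 (camera adjusted p = 2.17e-09; adjusted p = 0.235 with an estimated correlation). Cebpe, a transcription factor of granule formation, fell 8.51-fold (adjusted p = 0.00119) and the protease genes Prtn3 and Elane 1.95-fold and 1.81-fold. The call of Elane was kept without replicate 1 labelled knockout and lost without each other array (adjusted p from 0.0592 to 0.153). That of Prtn3 was lost without replicate 2 or 3 labelled knockout or control replicate 1, 3 or 4 (adjusted p from 0.062 to 0.105) and with quantile normalization (adjusted p = 0.0575). Replicate 1 labelled knockout stood apart in this list. S100a8, a calprotectin subunit singled out after its values were seen, read -0.181 on it against -3.17 and -3.35 on replicates 2 and 3, while the controls lay between -0.4 and 0.563. Without replicate 1 the list's median was -1.54 (camera adjusted p = 5.53e-18), and S100a8, S100a9 and Camp passed (adjusted p = 0.0017, 0.00266 and 0.00768). With all arrays these 3 genes did not pass (adjusted p = 0.198, 0.236 and 0.288).

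In the T cell receptor complex and signalling list, 6 of 23 rose and none fell, with a median of 0.57 (camera adjusted p = 2.13e-09; adjusted p = 0.0344 with an estimated correlation), and 10 rose adjusted over the list alone. The median was 0.37 with normexp and percentile scaling and 0.24 without a filter. The list members Cd3e and Cd3g, chains of the receptor complex, had log2 fold changes of -0.05 and 0.72. They did not pass (adjusted p = 0.915 and 0.699). Rag1 and Rag2, the recombinase of antigen receptor genes, rose 12.0-fold (adjusted p = 0.000269) and 4.10-fold (adjusted p = 0.00234), Trat1, a T cell receptor adaptor, 5.36-fold (adjusted p = 0.00018) and the costimulatory receptor gene Icos 5.16-fold (adjusted p = 0.0186). The call of Icos was lost with the common floor (adjusted p = 0.0563) and without control replicate 1 or replicate 1 or 3 labelled knockout (adjusted p from 0.0503 to 0.0734). Among 14 T lymphocyte transcription factors, Gata3, Tcf7 and Tox rose, 4 members adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00613; adjusted p = 0.0742 with an estimated correlation). Without Gata3 and Tcf7, which the study chose, that list had a median of 0.04 and did not pass (camera adjusted p = 0.145). With all its members, the median was -0.07, 0.40 and 0.04 without replicate 1, 2 or 3 labelled knockout, and 0.20 and 0.05 without control replicate 3 or 4. The call of Tox was lost without replicate 1, 2 or 3 labelled knockout (adjusted p from 0.0599 to 0.0742). Of 16 natural killer and innate lymphoid genes, 5 rose and 7 rose and 5 fell adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.0104; adjusted p = 0.292 with an estimated correlation). The median was 0.20 with normexp and percentile scaling, 0.17 over genes well above background on all arrays and -0.29 without a filter, where the call was lost (camera adjusted p = 0.116). Gzma, a granule protease, rose 10.3-fold and Nkg7 4.71-fold. Of 18 B lymphocyte genes, Rag1, Mzb1 and Cd72 rose, 4 rose and 1 fell adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.00189; adjusted p = 0.0742 with an estimated correlation). That median was 0.04 without replicate 1 labelled knockout, 0.04 over genes well above background on all arrays and -0.02 with normexp and percentile scaling, while the list's call was kept. Cd72 lost its call with the replicate block (adjusted p = 0.107).

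Targets of p53, the transcription factor of the DNA damage response, were higher: 6 of 14 rose and none fell, 8 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 1.16e-09; adjusted p = 0.0659 with an estimated correlation). Besides Phlda3, Zmat3 rose 5.85-fold (adjusted p = 0.000431), the death receptor gene Tnfrsf10b 3.60-fold (adjusted p = 0.00849) and Trp53inp1 3.13-fold (adjusted p = 0.00116). Of 2 members singled out after their values were seen, the cell cycle inhibitor Cdkn1a rose 2.23-fold (adjusted p = 0.00495), and Mdm2 had a log2 fold change of 0.30 (SE 0.18, adjusted p = 0.532). The call of Cdkn1a was lost with the replicate block (adjusted p = 0.0883). Of 15 immediate early and heat shock genes, none passed, 3 were lower adjusted over the list alone, and the list was shifted with a median of -0.38 (camera adjusted p = 0.0301; adjusted p = 0.348 with an estimated correlation). The call was lost without replicate 2 labelled knockout (adjusted p = 0.354), control replicate 1 (adjusted p = 0.0784) or control replicate 3 (adjusted p = 0.0567).

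Among the dendritic cell lists, those of plasmacytoid cells and of maturation were called by camera, in neither case with an estimated correlation. The directional test of fry called both and also the type 2 conventional list (adjusted p = 0.0123). Its mixed test called these as well, and further the lists of development regulators (adjusted p = 0.0131) and type 1 conventional genes (adjusted p = 2.54e-05). That of MHC class II presentation was not called by it (adjusted p = 0.166). None of 20 dendritic cell development regulators passed (median -0.10, camera adjusted p = 0.38), and neither did any of 13 genes of MHC class II presentation (median -0.18, camera adjusted p = 0.151), although the latter list was called without control replicate 2 (camera adjusted p = 0.0165). With 1 array left out, these medians ranged from -0.21 to -0.04 and from -0.21 to -0.12. Among type 1 conventional dendritic cell genes, Gcsam rose 4.74-fold, alone also when adjusted over the list alone, while the median was -0.21 and the camera test pointed up without passing (adjusted p = 0.734). That median was -0.08, -0.02 and -0.11 without replicate 1, 2 or 3 labelled knockout, and 0.06 without control replicate 4. Among type 2 genes, Ltb rose 3.41-fold and Clec10a and Itgam fell 4.86-fold and 1.62-fold, with 1 higher and 4 lower adjusted over the list alone (median -0.20, camera adjusted p = 0.0977). The call of Itgam was lost without replicate 1 or 3 labelled knockout or control replicate 1, 3 or 4 (adjusted p from 0.0885 to 0.195), with quantile normalization (adjusted p = 0.0737) and with both other rules for choosing probes (adjusted p = 0.0539 and 0.179). The plasmacytoid list had a median of -0.19 (camera adjusted p = 0.0301; adjusted p = 0.276 with an estimated correlation), with 1 higher and 5 lower adjusted over the list alone. In it Dntt, the terminal transferase of antigen receptor joining, rose 4.63-fold and Lair1 fell 1.80-fold. Klk1 was well above background on 1 of 3 arrays labelled knockout and fell 4.95-fold with each array's own floor (adjusted p = 0.00046) and 2.14-fold with the common floor (adjusted p = 0.0316). The list lost its call without replicate 2 or 3 labelled knockout (adjusted p = 0.129 and 0.0914) or control replicate 1 (adjusted p = 0.108). Lair1 lost its call without replicate 1, 2 or 3 labelled knockout or control replicate 1 or 4 (adjusted p from 0.0756 to 0.128).

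Siglech, a plasmacytoid marker singled out after its value was seen, had a log2 fold change of 0.01 (SE 0.21, adjusted p = 0.989), but its probe with the largest interquartile range gave -1.09 (adjusted p = 0.0424), so its probes disagree. In the maturation and costimulation list, Tnfsf4 and Socs2 rose and Il15 fell, with 3 higher and 1 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.0196; adjusted p = 0.292 with an estimated correlation). The list lost its call without replicate 1, 2 or 3 labelled knockout (medians 0.07, 0.22 and 0.05, adjusted p = 0.303, 0.0731 and 0.211) or control replicate 4 (adjusted p = 0.0742), and its median was -0.04 with normexp and percentile scaling. Of the 7 arrays left out in turn, Socs2 kept its call without control replicate 2 and lost it without each of the others (adjusted p from 0.052 to 0.15). It also lost it with normexp and percentile scaling (adjusted p = 0.0609), the probe of largest interquartile range (adjusted p = 0.0532), genes measured in both groups (adjusted p = 0.0516) and the common floor (adjusted p = 0.0713). Il15 lost its call without replicate 1 or 3 labelled knockout (adjusted p = 0.056 and 0.0798).

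**Figure D3:**
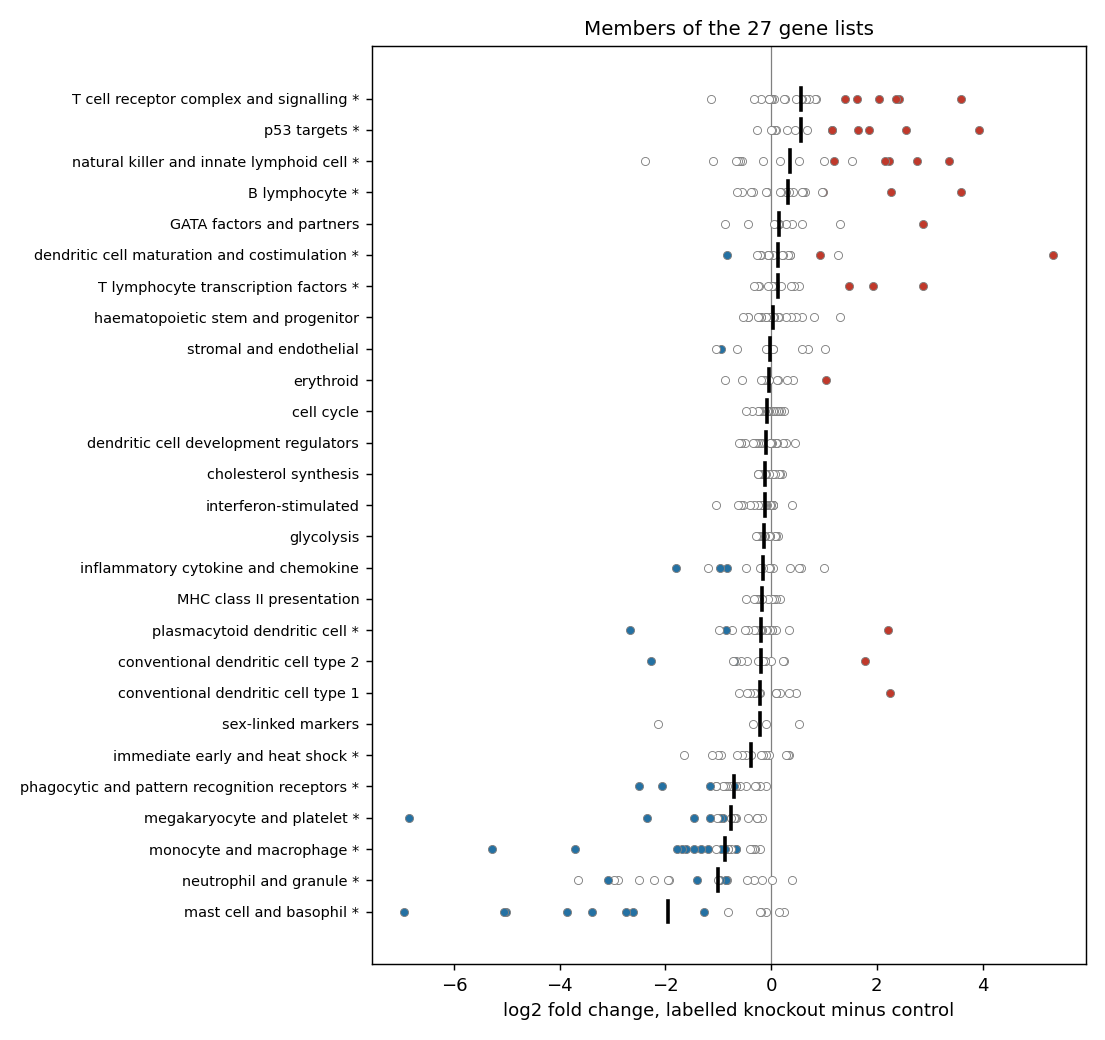
Log2 fold change (arrays labelled knockout minus controls, horizontal axis) of each tested member of the 27 gene lists, 1 row per list. Filled points passed the threshold, open points did not, black bars mark list medians, and asterisks mark the 13 lists called by camera, from the mast cell and basophil list at -1.94 to the T cell receptor list at 0.57.

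The remaining 10 lists were not called by camera or by the directional test of fry. The mixed test of fry, which takes changes in either direction, called 5 of them, those of inflammatory (adjusted p = 2.54e-05), GATA factor (adjusted p = 0.00321), stromal (adjusted p = 0.00411), erythroid (adjusted p = 0.00569) and stem and progenitor genes (adjusted p = 0.0333). Cell cycle genes, of which none of 25 passed, had a median of -0.07 (camera adjusted p = 0.672), glycolysis genes -0.13 (camera adjusted p = 0.222), cholesterol synthesis genes -0.11 (camera adjusted p = 0.657) and interferon-stimulated genes -0.12 (camera adjusted p = 0.323), with no member of these past the threshold, also adjusted over each list alone. With 1 array left out, the medians ranged from -0.14 to -0.02 for cell cycle, -0.19 to -0.08 for glycolysis and -0.15 to -0.05 for cholesterol synthesis genes. The interferon-stimulated list was called without replicate 1 labelled knockout (median -0.50, camera adjusted p = 0.000817), without control replicate 4 (median -0.33, camera adjusted p = 0.0092) and with array weights (median -0.43, camera adjusted p = 0.0116), and its median was 0.14 without replicate 3 labelled knockout. Haematopoietic stem and progenitor genes had a median of 0.03 (camera adjusted p = 0.427) with none of 21 past it. With 1 array left out, the medians of the stem and progenitor (-0.088 to 0.056), erythroid (-0.092 to 0.030) and stromal lists (-0.10 to 0.057) took both signs. Inflammatory cytokine and chemokine genes had a median of -0.16 (camera adjusted p = 0.485), with Il6, Ccl6 and Ccl9 lower and 2 higher and 5 lower adjusted over the list alone. That median was -0.34 and 0.01 without replicate 1 or 3 labelled knockout, and 0.02 and -0.31 without control replicate 2 or 4. Il6 lost its call without each of the 7 arrays (adjusted p from 0.0501 to 0.113), Ccl9 without replicate 1 or 3 labelled knockout or control replicate 3 or 4 (adjusted p from 0.0669 to 0.136) and Ccl6 without replicate 1 labelled knockout (adjusted p = 0.0592). With quantile normalization Il6 and Ccl9 did not pass (adjusted p = 0.0631 and 0.0518), nor did Il6 with the common floor (adjusted p = 0.0763), genes measured in both groups (adjusted p = 0.0515) or the probe of largest interquartile range (adjusted p = 0.0545). Erythroid genes had a median of -0.04 while the test pointed up (camera adjusted p = 0.672), with Car2 higher and 1 higher and 1 lower adjusted over the list alone. The call of Car2 was kept without control replicate 4 and lost without each of the others (adjusted p from 0.0753 to 0.185), and also lost with the common floor (adjusted p = 0.0798), quantile normalization (adjusted p = 0.0565), genes measured in both groups (adjusted p = 0.0515) and the probe of largest interquartile range (adjusted p = 0.0563). The list of GATA factors and partners had a median of 0.15 (camera adjusted p = 0.0931), with Gata3 higher and 2 higher and 1 lower adjusted over the list alone. It was called without control replicate 2 (median 0.23, camera adjusted p = 0.0289), with normexp and percentile scaling (camera adjusted p = 0.0351), without a filter (camera adjusted p = 0.0378) and with array weights (camera adjusted p = 0.0305). Stromal and endothelial genes had a median of -0.02 while the test pointed up (camera adjusted p = 0.788), with Acta2 lower on both adjustments, a call lost without control replicate 1, 2 or 3 or replicate 1 or 3 labelled knockout (adjusted p from 0.0501 to 0.135). The sex-linked markers had a median of -0.22 (camera adjusted p = 0.664), and of -0.35 and -0.13 without replicate 2 or 3 labelled knockout. In all, camera called 13 of 27 lists with the preset correlation and 3 with an estimated one, those of mast cells and basophils, monocytes and macrophages, and the T cell receptor. One regrouping of the same arrays that moved control replicate 2 to the other side gave 15 called lists.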

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

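The tests read from the mast cell genes, from the stress genes, from bright p53 targets, from feeder cell genes, from mature lymphocyte genes and from 3 lists apart from the B lymphocyte one were chosen after the results were seen, as was the question of where the probe lies, and the others before. Among 108 values tested within the 4 controls, 5 stood apart by a gap larger than chance gives in about 1 of 20 groups, so this number is no more than chance gives. Ddit4l was -6.21 in control replicate 1 against -7.81 to -7.55 in the others. Zfp365 was -3.14 in control replicate 2 against -5.08 to -4.93. In control replicate 3, Il18r1 was -2.52 against -2.21 to -2.20, and Hk2 was 4.78 against 4.13 to 4.21. The dimmest signal well above background was -5.32 in control replicate 4 against -5.60 to -5.56. Outside the named genes, 73 of 15306 tested probes without a gene name were higher in the arrays labelled knockout and 14 lower.

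The Gata2 probe was brighter in the arrays labelled knockout. If the labels of the groups had been exchanged, mast cell and basophil genes, whose cells are known to need GATA2, would be higher there. Their median was -1.94, with a standard error of the list's mean of 0.62, which argues against an exchange as far as that need holds. Such an error measures the spread over list members, which are not independent, and not the spread between arrays. Esr1, part of which an inducible Cre can carry, had a log2 fold change of 0.071 (SE 0.22) and decided nothing. The scanner files hold 0 columns of probe sequence, so a probe outside the deleted part stays open.

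Of 14 p53 targets, 6 were higher in the arrays labelled knockout, and the list was called by camera with its preset correlation but not with an estimated one (adjusted p = 0.0659). General stress of the kind that raises immediate early and heat shock genes is argued against. Their median was -0.38, with a standard error of the list's mean of 0.15. The fall of that list was not called with an estimated correlation (camera adjusted p = 0.348). Stress that does not raise these genes was not tested. Background differences at dim spots are argued against as well, since all 14 members were well above background on all arrays, with a median of 0.57. The presence of the Cre, given to the knockout group alone, cannot be told apart from a loss of Gata2, because the labels name 0 arrays with the Cre and an intact gene, and the deletion itself is known from the label alone. A response of the cells to a loss of Gata2 stays open and untested.

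With camera's preset correlation, lymphoid lists were higher and myeloid lists lower in the arrays labelled knockout. With an estimated correlation the T cell receptor, monocyte and mast cell lists kept their call, and the T transcription factor (adjusted p = 0.0742), natural killer (0.292), B lymphocyte (0.0742), neutrophil (0.235) and phagocytic (0.0659) lists lost it. The T transcription factor list also lost its call without the 2 of its genes the study names (adjusted p = 0.145). Background differences at dim spots are argued against as the whole cause for the T cell receptor, monocyte and macrophage, and mast cell and basophil lists, since over genes well above background on all arrays these 3 kept their call, with medians of 0.58, -0.82 and -1.04. The mast cell and basophil median had been -1.94 over all members, so a part of that shift from background stays open. The B lymphocyte list also kept its call there, making 4 of 4, but its median fell from 0.31 to 0.04, so a kept call did not settle that list and its background stays open. More feeder bone marrow cells of all kinds cannot be told apart either. S100a8, S100a9, Camp, Ltf, Ngp and Hba-a1 had a median of -2.36, with a standard error of their mean of 0.55. Of these 6, however, 5 belong to the lower neutrophil list itself and 0 passed the threshold. More mature lymphocytes cannot be told apart from a change within the cultured cells. The 5 tested genes of mature lymphocytes had a median of 0.18, with a standard error of their mean of 0.17. The abundant Cd79b and Cd3e had log2 fold changes of -0.09 and -0.05. For these lists too, the presence of the Cre cannot be told apart from a loss of Gata2. A change of the cells' own program with Gata2 stays open and untested.

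A chance split of the arrays is argued against for the count of genes: 1 of 35 splits, the real one, gave 418 genes, and the highest other gave 11. That is the smallest share that 35 splits can give. The splits cannot tell targeting of Gata2 from the presence of the Cre, which only the knockout group carried. Nor can they tell it from the slide row that each group had to itself, or from replicates of a shared animal. The splits do not exclude chance for the count of lists called by camera with its preset correlation: 2 of 35, the real one included, gave at least the real 13. The highest other gave 15, with control replicate 2 moved to the side of the arrays labelled knockout, and the median of the others was 3. That regrouping keeps the 3 arrays labelled knockout together and so can hold much of the group difference. The count of splits therefore cannot decide the question for lists.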

How the results depend on the processing

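The floors, the filter on genes measured in both groups, and the lists without study-named genes were chosen after seeing the data. Gata2 kept its direction and call under all 24 alternatives run, between 2.68 and 2.89 with 1 array left out. Without a filter on background, 365 genes were higher and 2483 lower, and array weights gave 699 and 822. Each array's own floor gave 311 lower. The replicate block over 6 arrays gave 86 and 95, with 83 and 80 of the main calls among them. Among named genes it lost the calls of Cdkn1a, Maf, Fcer1a and Cd72, and of others that further alternatives also lost. The labels do not say whether equal replicate numbers mark a pairing. As deviations from group means, correlations of same-numbered arrays were -0.17, -0.16 and -0.01, and no array labelled knockout correlated best with its own number. So few values cannot exclude a pairing. With 1 array left out, higher genes ranged from 88 to 225 and lower genes from 105 to 178. Leaving out an array labelled knockout left 164 of the 217 higher genes tested.

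With an estimated correlation 3 lists were called. Fry's directional test called 13, with the type 2 dendritic list added and the immediate early list lost, and its mixed test 21. Medians of the lists that lost their call with an estimated correlation were unchanged by construction: -0.19 (plasmacytoid), 0.13 (maturation), -1.01 (neutrophil), -0.70 (phagocytic), 0.13 (T transcription factors), 0.35 (natural killer), 0.31 (B lymphocyte), -0.75 (megakaryocyte), 0.57 (p53) and -0.38 (immediate early). The plasmacytoid list lost its call with normexp and quantile normalization (-0.061), normexp and percentile scaling (-0.19), quantile normalization (-0.10), no filter (-0.19), probes bright on all arrays (-0.18), both floors (-0.19) and 3 of 7 arrays left out, where it ranged from -0.25 to -0.13. The maturation list lost it with normexp and quantile normalization (0.082), quantile normalization (0.15), probes bright on all arrays (0.044), the replicate block (0.11), genes measured in both groups (0.044) and 4 of 7 arrays left out, ranging from 0.052 to 0.22. The immediate early list lost it without a filter (-0.38), with array weights (-0.35), both floors (-0.38), fry (-0.38) and 3 of 7 arrays left out, ranging from -0.51 to -0.27. The natural killer list lost it without a filter (-0.29), and T transcription factors without the study-named genes (0.043). The cause was not tested.

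Of named genes under alternatives, 2214 results kept their side of the threshold, 175 lost the call and 20 gained it. Siglech reversed at -1.09 with the probe of largest interquartile range, where it passed. Direction was not compared where a gene passed in neither fit. Siglech, Tcf4, Cd3e and Esr1, which did not pass in the main fit, took both signs with 1 array left out. No called list reversed in camera's direction, but 4 medians changed sign: natural killer without a filter (-0.29), T transcription factors without replicate 1 labelled knockout (-0.07), and maturation (-0.04) and B lymphocyte (-0.02) with normexp and percentile scaling. A slide block was not run, with 1 slide. Signal over background limits the folds of dim genes.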

Other observations

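Ranked among genes measured well above background in both groups, a ranking chosen after seeing the data, further large rises after Matn1, Zfp365, Inka2 and Phlda3 were in Rag1, Gzma, Lypd6b (9.31-fold), Lax1 (9.13-fold), Zfp462 (9.07-fold) and Ddx4 (8.67-fold). Lax1, an adaptor that dampens lymphocyte signalling, had an adjusted p of 0.00221. Lypd6b and Zfp462 were each well above background on 1 of 4 controls and Ddx4, a helicase known from germ cells, on 3 of 4, and their rises were 4.95-fold, 3.82-fold and 6.27-fold with each array's own signal floor. The call of Lypd6b was lost without replicate 1 or 2 labelled knockout (adjusted p = 0.0636 and 0.0521) and that of Zfp462 without replicate 2 or 3 (adjusted p = 0.0553 and 0.0614). That of Ddx4 was lost without replicate 1, 2 or 3 labelled knockout or control replicate 1 or 3 (adjusted p from 0.0536 to 0.13). Further large falls after Prss34, Thbs1, Klk1b11, Tspan12, Fcer1a and Cpa3 were in Grtp1 (20.4-fold), Fyb2 (20.1-fold), Dennd2a (18.4-fold) and Rnase2a (15.9-fold). Of these, Grtp1 and Rnase2a were well above background on 2 of 3 arrays labelled knockout and Fyb2 on 1 of 3, and with each array's own floor Grtp1 fell 17.7-fold and Fyb2 18.7-fold. With a floor common to all arrays Grtp1 and Fyb2 each fell 10.6-fold. Rnase2a belongs to an eosinophil ribonuclease family of closely related genes, and whether its probe also reads its relatives was not tested.

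Xist and Ddx3y, expressed from the inactive X and the Y chromosome, were both well above background on 7 of 7 arrays. The arrays therefore held signal of both kinds in each group, and the labels do not give the sex of donors or feeder mice.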
